A study of Arabidopsis thaliana with 12 samples.

How the data were processed

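RNA was sequenced from Arabidopsis thaliana seedlings of the wild type Col-0 and of the mutant line camta6-5, each grown with 0 or 200 mM NaCl for 16 hours. The 12 libraries form 4 groups of 3. The labels call the material pre-germinated seedlings and name a kit that does not mark the strand of the transcript. The deposited table held raw read counts per gene, as whole numbers with unequal totals and no normalization by the authors. Per the labels, the authors used cutadapt 1.9, TopHat2 2.1.0, Bowtie2 2.2.6, HTSeq 0.6.1 and DESeq2 1.10.0 with the genome build TAIR10, without stated settings. How the authors treated reads that fall on more than 1 gene is therefore not known, and counts of near-identical genes or of genes that overlap a neighbour are uncertain in that respect.

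The table listed 33602 genes, of which 8362 had no count in any library and 32835 were found in the reference annotation. Totals ran from 29473212 to 35450685 counts per library. At that depth a count of 0 over a group allows up to 0.029 to 0.032 CPM (counts scaled to a common library size), taking 3 counts over the group as the limit. Such limits and the 95% intervals of ratios cover counting error only, since reads without molecular identifiers are not independent molecules.

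The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups (a minimum count of 10 and a minimum total of 15), which left 18515 genes. TMM factors scaled the libraries. A quasi-likelihood model with 1 mean per group and 8 residual degrees of freedom was fitted to all 12 libraries, and each comparison was tested with edgeR's two-sided quasi-likelihood test. Adjusted p is by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A gene past it is described as higher, lower, risen or fallen, and counts are also given for changes of at least 2-fold. The 5 comparisons were NaCl against control in each genotype, camta6-5 against wild type at each treatment, and the genotype by NaCl interaction, which is the response in camta6-5 minus the response in wild type. CPM are given with TMM scaling as mean ± SD of 3 libraries, and log2 fold changes as estimate ± SE. That SE was derived from the test, as the absolute estimate divided by the square root of the F statistic. For a gene with no count in a group, a lower bound of the fold was computed against 3 counts over that group. With 1 to 3 counts in a group, the ratio is given with its counting interval.

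Before the data were examined, 22 gene lists with 421 genes were fixed, of which 355 genes were tested. They cover the CAMTA family, sodium, potassium and proton transport, abscisic acid (ABA) signalling, ABA metabolism, late embryogenesis abundant proteins, seed storage and oil bodies, reserve mobilisation, gibberellin, cell wall loosening, photosynthesis, cell division, osmoprotectants, reactive oxygen species, calcium sensing, salicylic acid and defence, CBF and DREB factors, heat shock, ethylene, auxin, aquaporins, endosperm and seed coat. Each list was tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, with camera and an estimated correlation, and with fry. Adjusted p is over the 22 lists of a comparison. A further 6 lists (ER body, cytosolic ribosomal proteins, organelle ribosomal proteins, nucleolar and rRNA processing, proteasome subunits, histones) were added after the data had been seen. Their adjusted p is over these 6 lists of a comparison, apart from the 22.

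The rule for named genes was also fixed beforehand. It takes CAMTA6 and 8 genes of salt and ABA responses (HKT1, SOS1, NHX1, AVP1, AKT1, ABI5, ABI4, RD29B) in every comparison. It takes the 5 largest rises and the 5 largest falls of each comparison among genes past the threshold whose 3 libraries of a group all lay above those of the other and whose higher group had at least 5 CPM. For the interaction the condition on single libraries was dropped. It takes up to 4 members with the smallest adjusted p from each list described. Which lists to describe, and which of the genes that the rule takes to print, was chosen after the results were seen. A few genes outside the rule are named as such.

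Promoters were the 1000 bases upstream of a gene. They were searched on both strands for the CGCG box, which CAMTA proteins are known to bind, and for the core of the ABA response element (ABRE). Genes with the motif were counted among nuclear genes called in the interaction and among all other tested nuclear genes, by two-sided Fisher's exact test with Benjamini-Hochberg over 4 tests. A promoter was found for 18445 of 18467 genes. The scan and the model fit were tested on simulated data. With 67 genes changed 2-fold, 62 were recovered for NaCl in wild type and 43 for the interaction, with 6 false calls in each over all fold sizes. The simulation of the fit changed 66 or 67 genes per fold size of 18515, in 1 group. In the data 77.5% of genes were called for NaCl in wild type and 48.1% for the interaction. How the fit performs when so many genes change was not simulated.

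The alternative settings fixed beforehand were RLE size factors, no filter, a stricter filter of at least 1 CPM in at least 3 libraries with a mean of at least 20 counts, DESeq2 1.42.0, limma voom, a fit of only the 2 groups compared, a replicate block, each library left out in turn, promoters of 500 bases and promoters stratified on expression. Chosen after seeing the data were a fit without ribosomal and mitochondrial genes, a fit without the 5 libraries richest in 18S rRNA, and promoters stratified on GC content. The labels give replicate numbers but not what a number shares, so no block entered the model. No library was left out of the reported values.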

Results

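Transcripts were counted by RNA sequencing in 12 libraries from Arabidopsis seedlings during early germination. CAMTA6 is a calmodulin-binding transcription activator, and camta6-5 is described by the labels as a mutant allele of its gene. The 4 groups of 3 libraries were wild-type control, wild-type NaCl (200 mM for 16 hours), camta6-5 control and camta6-5 NaCl. Total counts per library were 31024600 to 35450685 in wild-type control, 32887239 to 34849175 in wild-type NaCl, 30363367 to 33110796 in camta6-5 control and 29473212 to 35241845 in camta6-5 NaCl. The first principal component held 80.9% of the variance. The groups' mean scores on it were -74.44 ± 10.5 (SD, n = 3) for wild-type control, -75.76 ± 13.0 for camta6-5 control, 24.54 ± 8.65 for camta6-5 NaCl and 125.7 ± 6.62 for wild-type NaCl. The share of counts on 18S rRNA differed between libraries, with means of 0.205 ± 0.263% in wild-type control, 0.0422 ± 0.0283% in wild-type NaCl, 0.557 ± 0.459% in camta6-5 control and 0.353 ± 0.261% in camta6-5 NaCl.

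Counts of CAMTA6 itself (AT3G16940, TAIR10 chromosome 3, 5781775 to 5786280) were higher, not lower, in the libraries labelled camta6-5. Its mean was 17.84 ± 2.79 CPM in wild-type control and 34.8 ± 1.34 CPM in camta6-5 control, and 30.9 ± 2.84 CPM in wild-type NaCl and 43.9 ± 7.43 CPM in camta6-5 NaCl (SD, n = 3). Counts per gene do not show which part of the transcript was read, so they do not show whether a full-length transcript was made. For this reason the genotype is given below as the label of the library. Counts of HKT1 (AT4G10310), a sodium transporter, were 2 in 396069461 over the 12 libraries, and no comparison of it was possible at this depth.

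**Figure D1:**
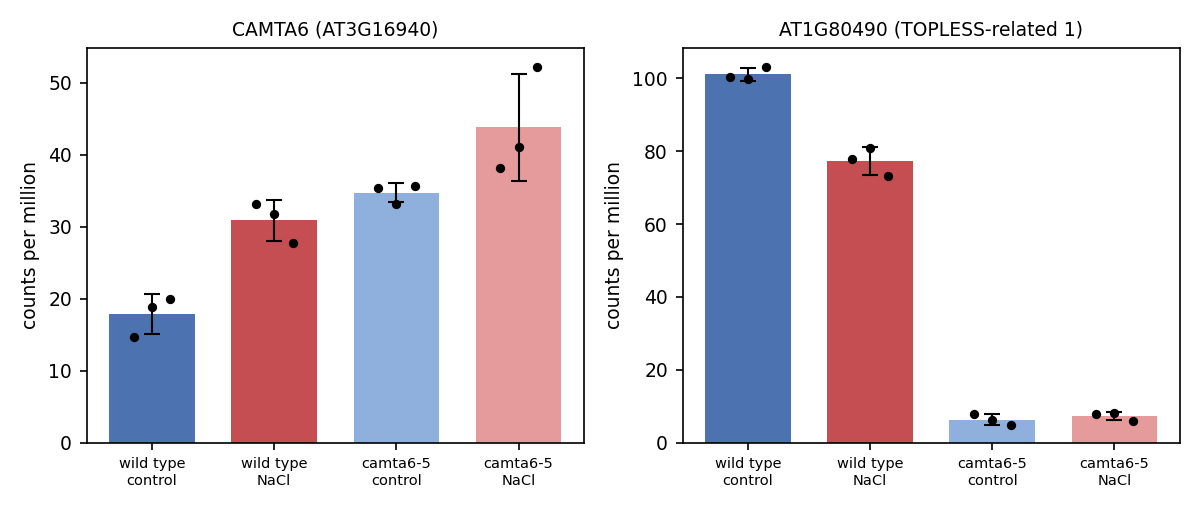
CPM of CAMTA6 and of AT1G80490 (TOPLESS-related 1) in the 4 groups, as bars for the mean, error bars for the SD and points for the 3 libraries. CAMTA6 was at 17.84 in wild-type control and 34.8 in camta6-5 control, and AT1G80490 at 101 and 6.34.

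The NaCl response of the wild type was asked first. All 15 tested genes for seed storage and oil body proteins rose, as did all 15 for late embryogenesis abundant (LEA) proteins, which protect cells during drying. The 2S albumin SESA3 went from 141 ± 12.1 to 1612 ± 173 CPM, the cruciferin CRU3 from 126 ± 22.3 to 2650 ± 248 CPM, the oil body protein CLO1 from 4.53 ± 0.93 to 184 ± 23.0 CPM, and the LEA protein EM6 from 43.1 ± 15.2 to 1220 ± 75.3 CPM (SD, n = 3). LEA14, RAB28, ECP31 and SESA1 rose by 2.80, 3.92, 6.08 and 3.22 on the log2 scale. Of 31 tested genes of ABA signalling, 21 rose and 9 fell. RAB18 went from 76.3 ± 14.9 to 2036 ± 185 CPM, RD29A from 1.06 ± 0.802 to 79.7 ± 14.1 CPM, and the protein phosphatase gene HAI2 from 4.44 ± 1.65 to 60.03 ± 3.34 CPM.

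In sodium, potassium and proton transport, 14 of 27 tested genes rose and 7 fell in wild type. The plasma membrane Na+/H+ exchanger gene SOS1 (AT2G01980, chromosome 2, 457010 to 463326) went from 12.7 ± 1.27 to 37.6 ± 0.536 CPM, a log2 change of 1.56 ± 0.0869 (edgeR adjusted p = 4.2e-09). The vacuolar exchanger gene NHX1 (AT5G27150, chromosome 5, 9553438 to 9557513) went from 10.1 ± 1.1 to 27.4 ± 2.65 CPM (log2 1.44 ± 0.0982, edgeR adjusted p = 2.28e-08). NHX3 and NHX6 rose by 2.76 and 1.21 on the log2 scale, and the potassium channel gene AKT1 rose from 16.9 ± 0.791 to 34.3 ± 7.46 CPM. The vacuolar proton pump gene AVP1 fell from 3238 ± 209 to 1529 ± 33.7 CPM, and the plasma membrane proton pump gene AHA2 fell from 535 ± 90.2 to 117 ± 9.89 CPM. AVP1, AKT1 and NHX3, and among the genes named further on MCM7, LHCB3, AT4G33666, APE2, PYK10, LEA7 and AT1G78050, overlap other annotated features, so part of their reads is of uncertain origin. The ABA transcription factor gene ABI5 rose from 56.2 ± 6.02 to 226 ± 12.6 CPM (edgeR adjusted p = 3.72e-09), ABI4 fell from 136 ± 13.7 to 87.1 ± 1.92 CPM (edgeR adjusted p = 5.13e-05), and the ABA-responsive gene RD29B rose from 7.90 ± 3.60 to 197 ± 25.7 CPM (edgeR adjusted p = 3.85e-08). CAMTA6 rose by 0.80 ± 0.131 on the log2 scale (edgeR adjusted p = 8.36e-05).

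In the lists of growth, more genes fell than rose in wild type. For photosynthesis, 23 of 26 tested genes fell and 0 rose, with RBCS2B, of the small subunit of Rubisco, falling by 4.55 on the log2 scale and the light-harvesting gene LHCB3 going from 11.8 ± 1.55 to 0.564 ± 0.106 CPM. PSBY and HEMA1 fell by 3.45 and 2.06 on the log2 scale. For cell division, 15 of 19 fell and 1 rose, with the replicative helicase gene MCM7 going from 37.1 ± 4.39 to 1.01 ± 0.28 CPM, PCNA1 from 30.9 ± 1.37 to 2.22 ± 0.366 CPM and MCM4 from 35.2 ± 3.16 to 4.18 ± 0.201 CPM. For cell wall loosening, 13 of 16 fell and 2 rose (among them EXPA15, by 1.44 on the log2 scale). The xyloglucan endotransglucosylase/hydrolase genes XTH16, XTH9 and XTH4 fell by 4.99, 5.65 and 6.20 on the log2 scale. For auxin response and transport, 12 of 14 fell and 0 rose, among them AUX1, LAX2, PIN2 and GH3.5, which fell by 2.63, 3.75, 3.54 and 2.80 on the log2 scale.

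The largest rises in wild type were of LTI30, a dehydrin gene (AT3G50970, 1.05 ± 0.669 to 175 ± 16.6 CPM), AT5G53260, AT4G33666, AT5G55135 and AT1G30860, by 6.60 to 7.40 on the log2 scale. The largest falls were of 5 genes with no count in wild-type NaCl. Against 3 counts over the group, the jacalin-related lectin gene JAL31 was at least 614-fold lower, AT5G26260 at least 426-fold, AT5G49800 at least 206-fold, the beta-glucosidase gene BGLU21 at least 203-fold and AT4G29690 at least 182-fold. In all, edgeR called 7011 genes higher and 7330 lower of 18515 tested, and 2499 higher and 3924 lower by at least 2-fold. Camera with the preset correlation gave adjusted p of 6.4e-07 for seed storage, 1e-06 for LEA, 1.5e-05 for photosynthesis, 0.00015 for cell division, 0.00028 for auxin, 0.0047 for cell wall loosening, 0.014 for ABA signalling and 0.24 for ion transport. With an estimated correlation 0 of the 22 lists passed in this comparison, where the lowest adjusted p was 0.36. The test fry, which asks whether a list's genes moved 1 way on balance, passed 18. Unlike camera, fry does not set a list against the other genes, and 77.5% of all tested genes were called here. A pass in fry therefore does not show that a list moved more than other genes. Adjusted over the list alone, the 8 counts were 15 and 0 higher and lower for seed storage, 15 and 0 for LEA, 21 and 9 for ABA signalling, 14 and 7 for transport, 0 and 23 for photosynthesis, 1 and 15 for cell division, 2 and 13 for cell wall loosening and 0 and 12 for auxin.

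**Figure D2:**
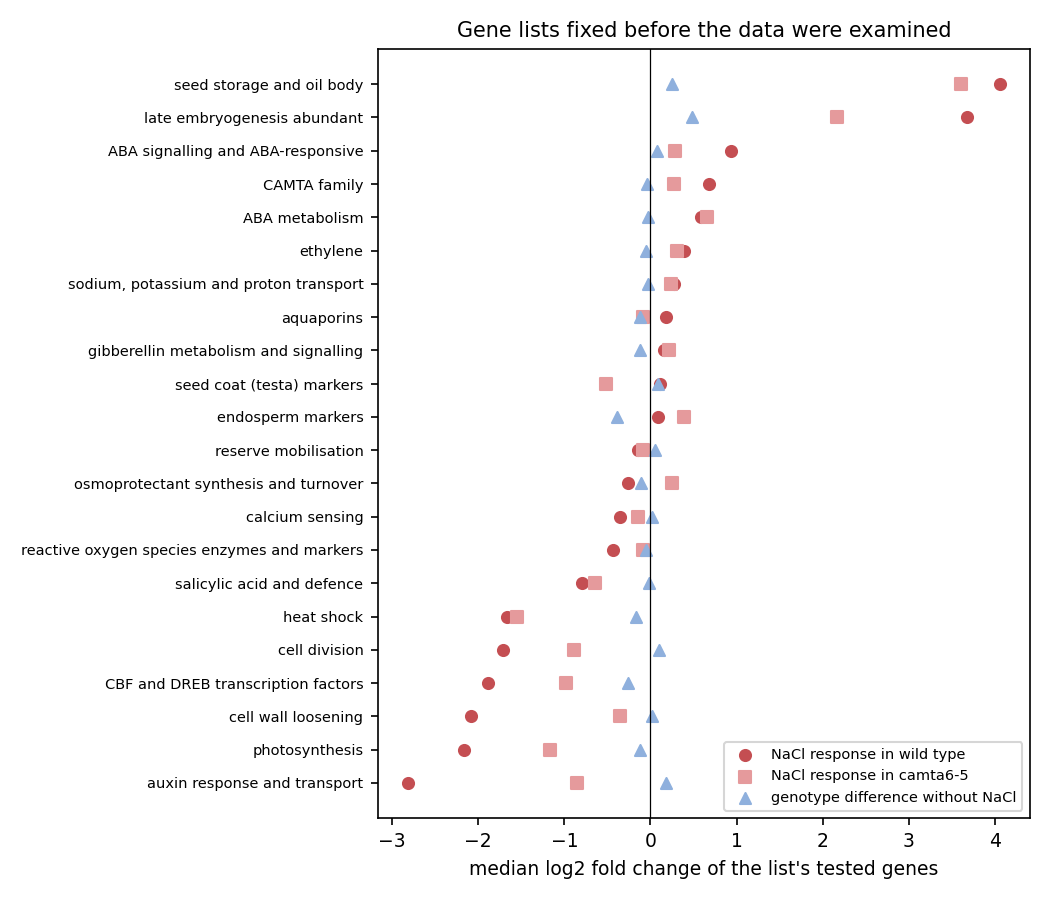
Median log2 fold change of the tested genes of each of the 22 lists (horizontal axis) for the NaCl response in wild type (circles), the NaCl response in camta6-5 (squares) and the genotype difference without NaCl (triangles). The seed storage list was at 4.06 and 3.60 in the NaCl responses and the auxin list at -2.82 and -0.86.

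The same treatment was then followed in the libraries labelled camta6-5. All 15 seed storage genes and all 15 LEA genes rose here too. CRU3 went from 140 ± 51.2 to 2242 ± 570 CPM, the cruciferin CRA1 from 582 ± 190 to 9091 ± 2410 CPM, EM6 from 43.9 ± 15.5 to 583 ± 104 CPM and SESA3 from 99.0 ± 22.2 to 444 ± 76.2 CPM (SD, n = 3). Of ABA signalling genes 14 rose and 6 fell, with RAB18 going from 76.2 ± 24.2 to 1443 ± 347 CPM, RD29A from 0.872 ± 0.41 to 19.0 ± 3.51 CPM and HAI2 from 6.29 ± 1.44 to 31.3 ± 3.77 CPM. The homeobox gene HB-12 fell by 3.65 on the log2 scale, which was not shown to differ from wild type (interaction 0.64 ± 0.4, SE, edgeR adjusted p = 0.203). Photosynthesis genes fell in 21 of 26 cases and rose in 0, cell division genes fell in 15 of 19 and rose in 2, cell wall genes fell in 8 of 16 and rose in 4, and auxin genes fell in 9 of 14 and rose in 1.

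SOS1 went from 13.0 ± 1.24 to 19.6 ± 0.375 CPM in camta6-5 (log2 0.60 ± 0.0874, edgeR adjusted p = 9.16e-05) and NHX1 from 9.55 ± 0.672 to 15.6 ± 0.429 CPM (log2 0.71 ± 0.0996, edgeR adjusted p = 6.71e-05). Of the transport list 12 genes rose and 7 fell, and the potassium transporter gene HAK5 rose from 1.45 ± 0.997 to 20.6 ± 1.37 CPM. The rise of HAK5 was not shown to differ from wild type (interaction 0.28 ± 0.45 on the log2 scale, edgeR adjusted p = 0.642). AVP1 fell by 0.36 ± 0.102 on the log2 scale (edgeR adjusted p = 0.00867), ABI5 rose by 1.05 ± 0.107 (edgeR adjusted p = 5.59e-06) and RD29B by 2.49 ± 0.311 (edgeR adjusted p = 2.72e-05). AKT1 rose by 0.61 ± 0.179 (edgeR adjusted p = 0.0105), a call that was lost without camta6-5 NaCl replicate 3 (log2 0.38, edgeR adjusted p = 0.0589). ABI4 was at -0.24 ± 0.0991 (edgeR adjusted p = 0.0524) and did not pass. It passed with RLE factors (edgeR adjusted p = 0.0329), the stricter filter (0.0458), DESeq2 (adjusted p = 0.0272), voom (0.0494), without ribosomal and mitochondrial genes (0.0485), without the 5 libraries richest in 18S rRNA (0.0358) and without camta6-5 control replicate 1 (0.023) or camta6-5 NaCl replicate 2 (0.0116). CAMTA6 was at 0.33 ± 0.127 (edgeR adjusted p = 0.0388). That call was lost with RLE factors (edgeR adjusted p = 0.0615), in DESeq2 (adjusted p = 0.0614), without camta6-5 control replicate 1, 2 or 3 (edgeR adjusted p = 0.0708, 0.101 and 0.0627) and without camta6-5 NaCl replicate 3 (log2 0.19, edgeR adjusted p = 0.206).

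The largest rises in camta6-5 were of MO1, GASA2, ECP31, AT2G41730 and AT1G30860, by 5.33 to 5.93 on the log2 scale. For MO1 and AT2G41730 the SD in camta6-5 NaCl (12 and 12.1 CPM) was as large as the mean (12.1 and 10.7 CPM), and limma voom did not call them (adjusted p = 0.0783 and 0.12). The largest falls were of AT2G45180, the vacuolar invertase gene ATBETAFRUCT4, BGLU28, the wax synthesis gene CER1 and ATMSRB5. ATBETAFRUCT4 had 470 counts without NaCl and 2 with it, a ratio of 251 (95% counting interval 69.2 to 2080). In all, edgeR called 5216 genes higher and 5085 lower, and 1117 higher and 1580 lower by at least 2-fold. Camera with the preset correlation gave adjusted p of 2.6e-11 for seed storage, 1.2e-08 for LEA, 6.7e-06 for photosynthesis, 1.6e-05 for cell division, 0.019 for auxin, 0.073 for ABA signalling, 0.17 for transport and 0.19 for cell wall loosening. With an estimated correlation 0 of 22 lists passed (lowest adjusted p = 0.51), and fry passed 18. Adjusted over the list alone, the counts became 16 higher and 8 lower for ABA signalling and 22 lower for photosynthesis, and those of the other 6 described lists did not change. Without the 5 libraries richest in 18S rRNA, a setting chosen after the data were seen, 2796 genes were higher and 2458 lower, with 1 library in each camta6-5 group.

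Without NaCl, edgeR called few genes between the genotypes, and genes not called may still differ. In the simulated data for this comparison, 35 of 67 genes changed 1.5-fold and 56 of 67 changed 2-fold were recovered. AT1G80490, the gene of the transcriptional corepressor TOPLESS-related 1 (chromosome 1, 30260903 to 30267038), had 101 ± 1.88 CPM in wild type and 6.34 ± 1.57 CPM in the libraries labelled camta6-5 (log2 -3.99 ± 0.151, edgeR adjusted p = 1.83e-08). CAMTA6 was higher in camta6-5 by 0.96 ± 0.131 on the log2 scale (edgeR adjusted p = 0.00661). APE2, the gene of a triose phosphate translocator of the chloroplast, had 17.36 ± 7.15 CPM in wild type and 82.0 ± 25.8 CPM in camta6-5, and the AINTEGUMENTA-like gene AIL1 had 11.99 ± 1.72 and 31.6 ± 2.04 CPM (SD, n = 3). AT2G07080 and AT1G22980 were also higher, and AT2G43590, AT5G33395, the lipid transfer protein gene LTP10 and the DREB gene DDF1 lower, by -2.62, -2.29, -1.37 and -1.12 on the log2 scale. GLK1, a transcription factor gene of the photosynthesis list, had 28.2 ± 3.90 CPM in wild type and 15.9 ± 1.1 CPM in camta6-5.

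Of the 8 salt and ABA genes, HKT1 had too few counts and the other 7 did not pass without NaCl. SOS1 differed by 0.03 ± 0.0887 on the log2 scale (edgeR adjusted p = 0.919), NHX1 by -0.08 ± 0.101 (0.799), AVP1 by -0.02 ± 0.102 (0.952), AKT1 by -0.23 ± 0.18 (0.667), ABI5 by 0.30 ± 0.107 (0.346), ABI4 by 0.03 ± 0.099 (0.942) and RD29B by 0.44 ± 0.326 (0.651). In all, edgeR called 16 genes higher and 24 lower in camta6-5 (9 and 9 by at least 2-fold), while 2037 passed an unadjusted p of 0.05. Of these 40 genes, 28 were called in the same direction with NaCl, 7 in the opposite direction and 5 not at all, where 62.3% of all tested genes were called. Camera with the preset correlation called the CBF and DREB list lower (1 of 7 genes lower, adjusted p = 0.00022) and the LEA list higher (0 of 15 genes called, adjusted p = 0.021), with adjusted p of 0.25 and 0.84 with an estimated correlation. Adjusted over the list alone, 2 of the CBF and DREB genes were lower and 0 of the LEA genes were called. The LEA call was lost without camta6-5 control replicate 1 or 2 (camera adjusted p = 0.36 and 0.078) and without wild-type control replicate 3 (0.3).

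The number of genes called without NaCl moved with the method: 33 higher and 42 lower with no filter, 72 and 88 in DESeq2, and 5 and 6 with only the 2 groups in the fit. The higher genes numbered 8 without camta6-5 control replicate 1, 8 without wild-type control replicate 1 and 10 without wild-type control replicate 3, and the split was 14 higher and 33 lower with no scaling factors (29.8% higher against 40%). AT2G43590 was not called without camta6-5 control replicate 2 or 3 or wild-type control replicate 1, 2 or 3 (edgeR adjusted p = 0.108, 0.134, 0.0783, 0.116 and 0.097), nor with the replicate block (log2 -2.71, edgeR adjusted p = 0.0605) or in voom (log2 -2.79, adjusted p = 0.0577). AT2G07080 was lost without camta6-5 control replicate 1 or wild-type control replicate 2 or 3 (edgeR adjusted p = 0.071, 0.0781 and 0.0576). LTP10 was lost without camta6-5 control replicate 1 or 2 (0.0559 and 0.0506), DDF1 without wild-type control replicate 2 (0.0509) and GLK1 without camta6-5 control replicate 1 or wild-type control replicate 1 (0.0595 and 0.0644). With only the 2 groups in the fit APE2 (log2 2.23, edgeR adjusted p = 0.0607), AT1G22980 (0.92, 0.0926), AT2G43590 (-2.63, 0.102), LTP10 (-1.38, 0.0532), DDF1 (-1.13, 0.0532) and GLK1 (-0.83, 0.0664) were not called. In the fits that left out 1 library AT1G80490, CAMTA6, AIL1 and AT5G33395 kept their calls. Without the 5 libraries richest in 18S rRNA, a setting chosen after the data were seen, 3 genes were higher and 1 lower. Of the genes named above as higher or lower without NaCl, AT1G80490 was called there (edgeR adjusted p = 1.81e-05), and the others were not. Only 1 camta6-5 control library was left in that fit. The log2 differences, reported and in that fit with its edgeR adjusted p, were 0.96 and 0.77 for CAMTA6 (0.255), 2.24 and 1.70 for APE2 (0.325), 1.40 and 1.45 for AT2G07080 (0.28), 1.40 and 1.47 for AIL1 (0.0511), 0.93 and 1.09 for AT1G22980 (0.188), -2.62 and -3.62 for AT2G43590 (0.103), -2.29 and -2.25 for AT5G33395 (0.0511), -1.37 and -1.53 for LTP10 (0.0894), -1.12 and -1.15 for DDF1 (0.325) and -0.83 and -0.87 for GLK1 (0.491). The groups compared had mean 18S rRNA shares of 0.557% and 0.205%.

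With NaCl, more genes of the growth lists were higher than lower in the libraries labelled camta6-5 against wild type, and more genes of ABA signalling and LEA proteins were lower than higher. MCM7 had 18.6 ± 1.44 CPM in camta6-5 NaCl and 1.01 ± 0.28 CPM in wild-type NaCl, and PCNA1 16.0 ± 0.497 and 2.22 ± 0.366 CPM (SD, n = 3). Of cell division genes 14 of 19 were higher and 0 lower, of cell wall genes 13 of 16 and 0, of auxin genes 12 of 14 and 0, and of photosynthesis genes 17 of 26 and 0. Of ABA signalling genes 20 of 31 were lower and 5 higher, and of LEA genes 8 of 15 were lower and 0 higher. Seed storage genes went both ways: SESA1 and SESA3 were lower by -1.83 and -1.86 on the log2 scale, CRA1 was higher by 0.97, and 2 of 15 were higher and 3 lower. The 2S albumin genes and the Rubisco small subunit genes are families of near-identical sequence, and how their reads were divided among the members is not known.

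SOS1 was lower in camta6-5 NaCl by -0.94 ± 0.0846 on the log2 scale (edgeR adjusted p = 1.24e-06), NHX1 by -0.81 ± 0.0956 (1.06e-05), AKT1 by -0.64 ± 0.173 (0.00585, and 0.277 without the 5 libraries richest in 18S rRNA), ABI5 by -0.65 ± 0.106 (0.000142) and RD29B by -1.71 ± 0.288 (0.000199). AVP1 was higher by 0.69 ± 0.103 (edgeR adjusted p = 6.85e-05), AHA2 by 1.79 ± 0.141 (4.61e-07), ABI4 by 0.42 ± 0.0995 (0.00227) and CAMTA6 by 0.50 ± 0.127 (0.00381). The largest differences were of genes nearly absent in wild-type NaCl. PYK10, the beta-glucosidase of ER bodies, had 863 ± 129 CPM in camta6-5 NaCl and 3.78 ± 1.87 CPM in wild-type NaCl, the lectin gene JAL34 66.1 ± 7.19 and 0.246 ± 0.148 CPM, AT5G23820 16.0 ± 3.78 and 0.106 ± 0.0866 CPM, and MLP28 10.5 ± 1.07 and 0.077 ± 0.0187 CPM. ATBARD1 had 518 counts against 2, a ratio of 272 (95% counting interval 74.9 to 2250). On the lower side were the transporter gene PGP9, CYP76C2, AT2G36540, LTI30 and AT1G80490, by -3.82, -3.67, -3.44, -3.42 and -3.40 on the log2 scale.

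In all, edgeR called 6259 genes higher and 5283 lower in camta6-5 NaCl than in wild-type NaCl, and 2377 higher and 945 lower by at least 2-fold. Camera with the preset correlation gave adjusted p of 0.00029 for auxin, 0.00029 for cell division, 0.00029 for cell wall loosening, 0.0042 for photosynthesis, 0.0042 for ABA signalling, 0.011 for LEA, 0.22 for seed storage and 0.54 for transport, where the list's median was 0.04 and its mean -0.02 with the test pointing down. With an estimated correlation 0 of 22 passed (lowest adjusted p = 0.39), and fry passed 18. Of 27 transport genes 6 were higher and 8 lower. Adjusted over the list alone, seed storage had 1 higher and 3 lower, and the counts of the other 7 described lists did not change. The share of counts on 18S rRNA also differed between these groups, with means of 0.353% and 0.0422%.

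**Figure D3:**
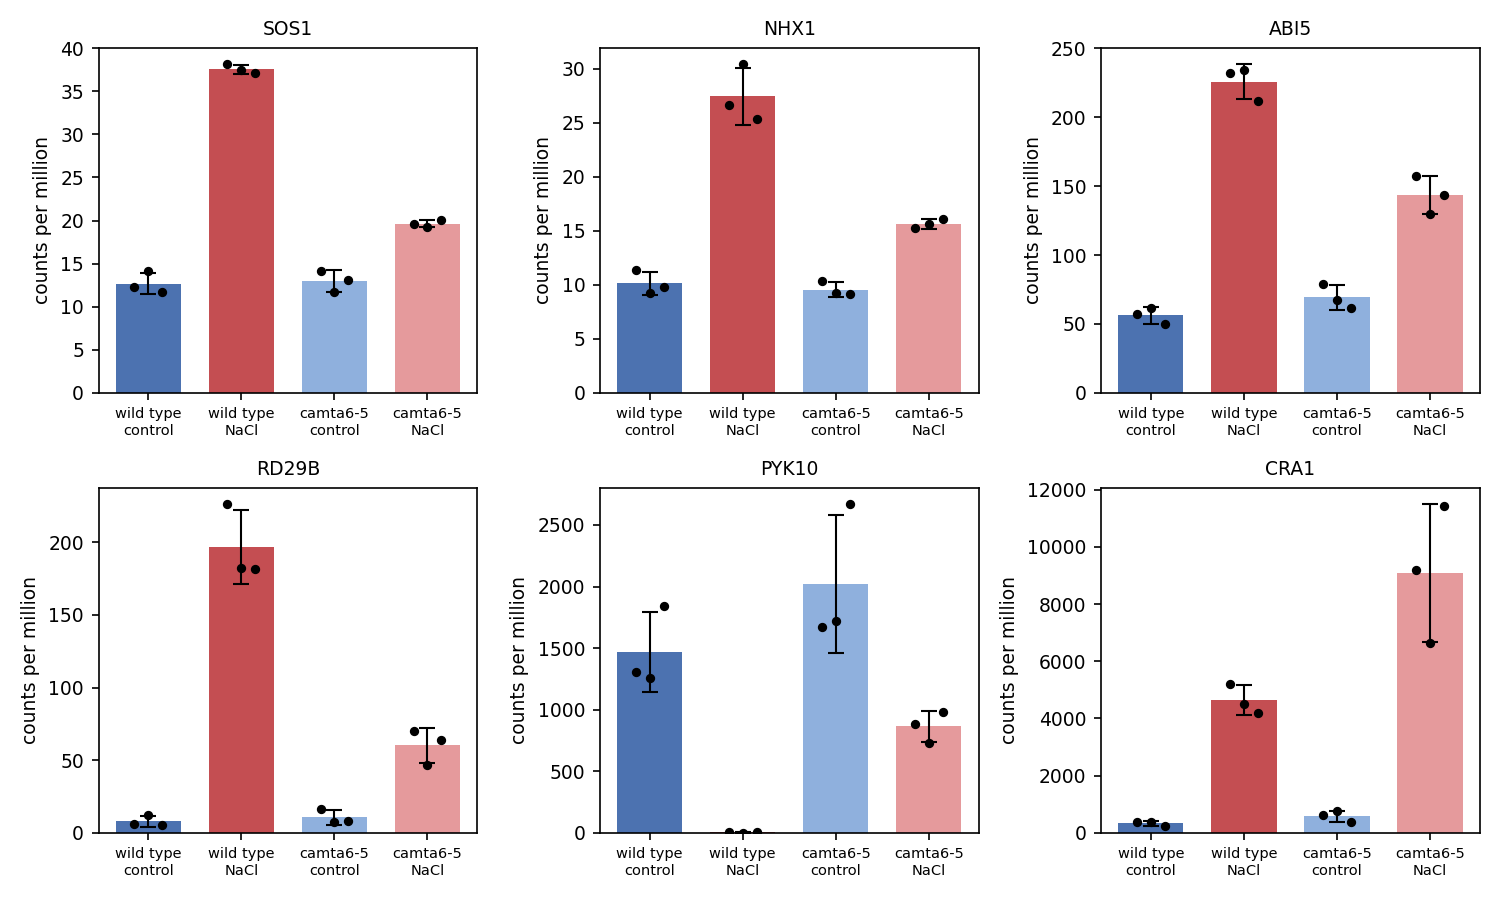
CPM of SOS1, NHX1, ABI5, RD29B, PYK10 and CRA1 in the 4 groups, as bars for the mean, error bars for the SD and points for the 3 libraries. SOS1 reached 37.6 in wild-type NaCl and 19.6 in camta6-5 NaCl, and PYK10 3.78 and 863.

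Whether NaCl acted differently in the genotypes was tested by the interaction. In the growth lists, 11 of 19 cell division genes had a positive interaction and 0 a negative one, as did 11 of 16 cell wall genes and 0, 10 of 14 auxin genes and 0, and 15 of 26 photosynthesis genes and 0. A positive value was not always a smaller fall: EXPA15 rose in both genotypes (log2 1.44 and 2.14), and EXPA9 fell in wild type (-1.86) and rose in camta6-5 (0.54). The interaction of MCM7 was 4.13 ± 0.226 on the log2 scale (edgeR adjusted p = 1.88e-07), of PCNA1 2.71 ± 0.176 (5.46e-07), of XTH16 2.50 ± 0.178 (1.07e-06), of AUX1 1.96 ± 0.145 (1.43e-06) and of LHCB3 3.20 ± 0.284 (4.94e-06). GH3.5, of an enzyme that conjugates auxin, fell in wild type and rose in camta6-5 (where the rise did not pass without the 5 libraries richest in 18S rRNA, log2 0.75, edgeR adjusted p = 0.0767), with an interaction of 3.69 ± 0.205 (edgeR adjusted p = 1.96e-07). For ABA signalling 13 of 31 genes had a negative interaction and 2 a positive one, for LEA 9 of 15 and 0, and for seed storage 5 of 15 and 0, among them LEA7 at -2.42 ± 0.343 (edgeR adjusted p = 0.00012), SESA3 at -1.35 ± 0.223 (0.000351) and ABI3 at -0.58 ± 0.107 (0.000708).

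SOS1 had an interaction of -0.97 ± 0.122 on the log2 scale (edgeR adjusted p = 5.3e-05), NHX1 of -0.73 ± 0.139 (0.000963), ABI5 of -0.96 ± 0.151 (0.000249), RD29B of -2.15 ± 0.432 (0.00134), AVP1 of 0.72 ± 0.145 (0.00136) and AHA2 of 1.92 ± 0.195 (1.22e-05). Without the 5 libraries richest in 18S rRNA, with 1 library in each camta6-5 group, RD29B (-1.37, edgeR adjusted p = 0.0677), AVP1 (0.42, 0.088) and ABI4 (0.13, 0.533) did not pass. AKT1, at -0.41 ± 0.25, did not pass (edgeR adjusted p = 0.196), though it did without camta6-5 NaCl replicate 3 (-0.64, edgeR adjusted p = 0.0232). CAMTA6, at -0.46 ± 0.182, did not pass either (edgeR adjusted p = 0.0512), with 0.03 to 0.0467 in DESeq2, voom, RLE, both filters, the block and the fit without ribosomal and mitochondrial genes, and 0.0493, 0.00968, 0.0223 and 0.0349 without camta6-5 control replicate 2, camta6-5 NaCl replicate 3, wild-type control replicate 3 and wild-type NaCl replicate 3. ABI4, at 0.40 ± 0.14 (edgeR adjusted p = 0.0317), was lost with RLE factors (0.0509). It was also lost without camta6-5 control replicate 1 or 3 (0.105 and 0.053), camta6-5 NaCl replicate 2 (0.0831), wild-type control replicate 1 (0.114) and wild-type NaCl replicate 1, 2 or 3 (0.0579, 0.0768 and 0.0648).

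In all, edgeR called 5017 genes with a positive interaction and 3888 with a negative one, and 2225 and 852 by at least 2-fold. The largest positive values among genes with counts in every group included JAL34 (8.02 ± 0.517), and the largest negative ones were of CYP71B26, the glucosyltransferase gene UGT74E2, AT4G18690, ATGSTU24 and AT1G78050, at -3.13, -3.02, -2.82, -2.78 and -2.70. Camera with the preset correlation gave adjusted p of 0.00022 for auxin, 0.00022 for cell wall loosening, 0.00035 for cell division, 0.0013 for photosynthesis, 0.0017 for LEA, 0.009 for ABA signalling, 0.051 for seed storage and 0.6 for transport, where the list's median was 0.13 and its mean -0.02 with the test pointing down. With an estimated correlation 0 of 22 passed (lowest adjusted p = 0.4), and fry passed 11. Of 27 transport genes 5 were positive and 7 negative. Adjusted over the list alone, 11 auxin genes were positive, and the counts of the other 7 described lists did not change. Without the 5 libraries richest in 18S rRNA, a setting chosen after the data were seen, 2607 genes were positive and 1970 negative.

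The responses of the genotypes, which share no library, were compared gene by gene. Both rose for 4268 genes and both fell for 4396, against 1975 and 2013 for independent lists, and 423 were called in opposite directions against 3991. Those 423 became 254, 235 and 271 without camta6-5 control replicate 1, camta6-5 NaCl replicate 1 and camta6-5 NaCl replicate 3. Across the 18515 genes, which are not independent replicates, Spearman's correlation was 0.80. Over the 15555 genes called in either genotype, the first principal component of the paired responses had a slope of 0.511, camta6-5 against wild type. That line is an orthogonal fit, which treats both responses alike, and not a regression. Of the 8905 genes with an interaction, 6459 (72.5%) had a smaller change in the same direction in camta6-5, 285 a larger one and 2161 estimates of opposite sign. CRA1 was higher in camta6-5 NaCl (9091 ± 2410 CPM) than in wild-type NaCl (4639 ± 518 CPM, edgeR adjusted p = 0.00535), while its interaction, 0.17 ± 0.36 on the log2 scale (SE), did not pass (edgeR adjusted p = 0.722).

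**Figure D4:**
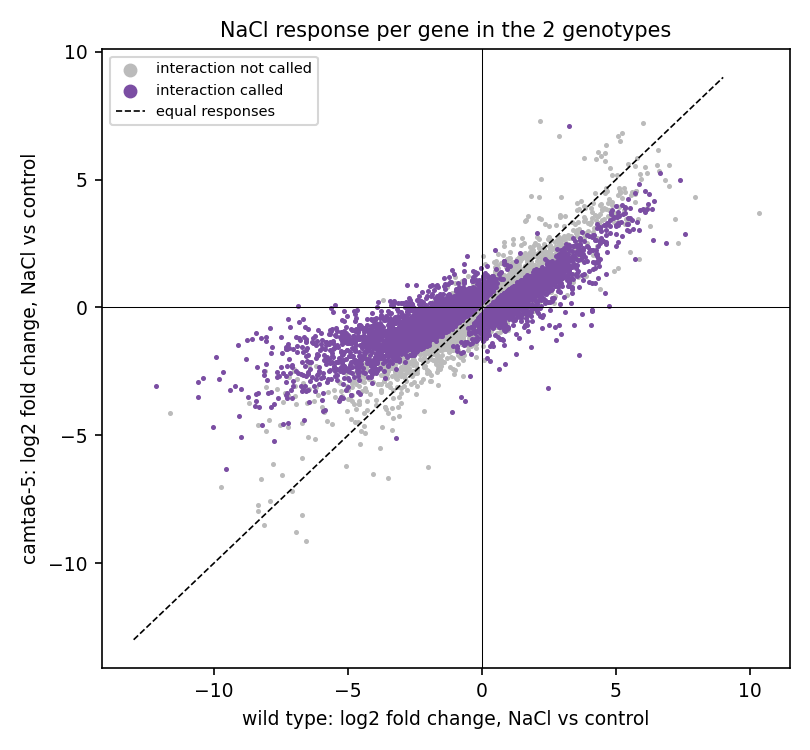
Each point is a gene, with its log2 fold change under NaCl in wild type (horizontal axis) and in the libraries labelled camta6-5 (vertical axis), in purple where the interaction was called. The dashed line marks equal responses, and the slope of the first principal component over the 15555 genes called in either genotype was 0.511.

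Promoters of the genes with an interaction were searched for a pair of motifs. The CGCG box stood in 19.6% of promoters with a positive interaction and 20.3% of all others (odds ratio 0.957, 95% interval 0.882 to 1.04, Fisher's exact test, adjusted p = 0.403), and in 20.6% with a negative interaction and 20% of all others (odds ratio 1.03, 0.946 to 1.13, Fisher's exact test, adjusted p = 0.457). The ABRE core stood in 17.5% of promoters with a negative interaction and 14.8% of all others (odds ratio 1.22, 1.11 to 1.34, Fisher's exact test, adjusted p = 2e-04). For a positive interaction it stood in 728 of 5013 and 2113 of 13432 promoters (odds ratio 0.91, 0.83 to 0.998, Fisher's exact test, adjusted p = 0.0873), and in promoters of 500 bases in 9.02% and 11.1% (odds ratio 0.793, 0.708 to 0.886, Fisher's exact test, adjusted p = 6.58e-05). Genes are not independent of each other, which the exact test does not take into account. The promoter sets were not matched on the wild-type NaCl response. Of the genes with an interaction, 72.5% had a smaller change in the same direction in the mutant line. Whether the ABRE excess goes with the response to NaCl itself was therefore not tested. Sequences other than the CGCG box that CAMTA proteins may bind were not searched for as such.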

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

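The tests of library scaling, swapped labels, a NaCl-like control, a chromosome segment, a mixture and the division of the paralog test by treatment were chosen only after the result was seen, while the paralog test as a whole and the counts over other splits of the libraries were set before. A difference between the genotypes' responses to NaCl, tested by the interaction in edgeR, brought the following results here. It was positive for 5017 genes and negative for 3888. Of 93 tested genes picked for the text, 57 had an interaction with counts in every group, 30 positive and 27 negative.

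Among genes of growth, the interaction on the log2 scale was 4.13 for MCM7, 2.71 for PCNA1, 2.24 for MCM4, 2.50 for XTH16, 2.86 for XTH9, 3.38 for XTH4, 1.95 for XTH5, 0.71 for EXPA15, 2.40 for EXPA9, 1.96 for AUX1, 2.99 for LAX2, 2.62 for PIN2 and 3.69 for GH3.5. Among nuclear genes tied to the chloroplast it was 1.88 for PSBY, 1.17 for RBCS2B, 3.20 for LHCB3, 0.57 for HEMA1, 1.44 for GLK1 and 2.85 for APE2. Among genes of ion transport it was -0.97 for SOS1, -0.73 for NHX1, -1.17 for NHX3, -0.49 for NHX6, -1.23 for CHX20, 0.72 for AVP1 and 1.92 for AHA2. Among genes of ABA signalling it was -0.96 for ABI5, 0.40 for ABI4, -0.58 for ABI3, -2.15 for RD29B, -1.81 for RD29A and -1.44 for HAI2. Among genes of seed and drought proteins it was -2.40 for LTI30, -0.53 for LEA14, -1.08 for RAB28, -1.09 for EM6, -2.42 for LEA7, -1.35 for SESA3, -1.25 for SESA1, -1.43 for SESA4 and -1.47 for CLO1.

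The genes nearly absent in wild-type NaCl had interactions of 8.02 for JAL34, 7.36 for PYK10, 6.79 for AT5G23820 and 7.15 for MLP28. Other positive values were 0.59 for AT1G80490, 0.70 for WSIP1, 2.08 for LTP10 and 1.15 for DDF1. Other negative values were -1.39 for AT5G55135, -2.50 for PGP9, -2.56 for CYP76C2, -3.13 for CYP71B26, -3.02 for UGT74E2, -2.82 for AT4G18690, -2.78 for ATGSTU24 and -2.70 for AT1G78050. For 6 more genes with an interaction, a group held 3 counts or fewer, so no fold is given. Their means in camta6-5 NaCl were 2.29 CPM for JAL31, 0.565 for AT5G49800, 0.65 for BGLU21, 1.05 for AT4G29690, 0.173 for ATMSRB5 and 5.22 for ATBARD1.

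Other splits of the same libraries were counted. For the interaction, 100 of 200 possible splits were counted, the real one among them and the rest drawn at random. The real split called 8905 genes. As many or more were called by 3 of the 100, with the real one counted, and the highest of the others called 9353. The 10 splits that part the NaCl libraries by genotype, the real one included, called at least 8232 genes each and the others 0 at most. So the count follows a structure of the samples, the genotype difference with NaCl. For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, and the real split, the 1 with the most calls, gave 14341 genes for NaCl in wild type (highest other 0), 10301 for NaCl in camta6-5 (0), 40 for the genotypes without NaCl (35) and 11542 with NaCl (0).

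CAMTA6 was higher in the libraries labelled camta6-5 without NaCl. Scaling is argued against, since the lowest log2 difference over TMM, RLE and no factors was 0.91, and so is a NaCl-like state of the camta6-5 controls, since the slope of the genotype difference without NaCl on the wild-type response was 0.0049. A swap of some libraries between the genotypes is argued against too, since of 200 ways to part the libraries 3 to 3 at both treatments, over all tested genes and without the labels, the labelled one parted 8 genes by at least 2-fold and the best other way 1. A swap of all labels cannot be told apart from an allele that still gives reads, since the difference of 0.96 has no sign that either forbids when counts per gene do not show the part read. A changed transcript of the camta6-5 allele may be the biological source, and it was not tested.

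AT1G80490 was lower in all 6 libraries labelled camta6-5. By the bound set before, that the related TOPLESS genes gain at least 50% of the CPM lost, reads shared with them stay possible, with a largest gain of 77.5%. That value is from the libraries with NaCl, where 1 gene, WSIP1 (TOPLESS), went from 138 in wild type to 230 CPM and 62.3% of all tested genes differed. Without NaCl the gain was 11.5% (10.9 ± 20.9 CPM, SE, of 94.7 CPM lost), and WSIP1 had 227 CPM in wild type and 233 in camta6-5. If shared reads were counted for the related genes, this argues against them as the source of the whole loss in those libraries. For a gain of 50% the error is too large to decide. A segment that differs between the lines cannot be told apart either, with 1 other called gene within 2 Mb and 0.95 from chance (Fisher's exact test, p = 0.62, odds ratio up to 6.28), and a second mutation in the line may be a source that was not tested.

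The NaCl response was smaller in the libraries labelled camta6-5. Scaling is argued against, since a scaling error shifts all genes alike, while the median interaction was -0.23 for genes rising in camta6-5 and 0.52 for genes falling there (-0.28 and 0.45 with RLE factors, -0.20 and 0.59 with none). A mixture of control-like and wild-type-like seedlings as the whole source is argued against, though weakly. Outside both on the same side, 6.92% of genes (6.82% with RLE factors) were called, over a bound of 5% that was set after the result was seen. Only 78 genes lay outside by at least 2-fold, so the argument rests mostly on smaller shifts. The median share of the way to wild-type NaCl was 0.373 for 1828 genes rising and 0.561 for 2310 genes falling at least 2-fold in wild type, of those with at least 5 CPM in the higher of its 2 groups. A partial mixture, a difference in seed lot or in the pace of germination and the genotype itself stay open, and none of the last 3 was tested.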

How the results depend on the processing

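The fits without ribosomal and mitochondrial genes and without the 5 libraries richest in 18S rRNA and the promoters stratified on GC content were chosen after seeing the data, and the other alternatives were planned. Under RLE factors, no filter, the stricter filter, DESeq2, voom, the block and the fit without ribosomal and mitochondrial genes, the counts for NaCl in each genotype, for the genotypes with NaCl and for the interaction stayed within 1.5 times the reported ones, and so did, with the 2 groups alone, those other than the interaction, which that fit does not cover. The genes called between genotypes without NaCl were 33 higher and 42 lower with no filter, 72 and 88 in DESeq2 and 5 and 6 with the 2 groups alone, where fewer libraries estimate the spread; for the others the cause was not tested. Leaving out each library in turn gave 8 to 17 higher (8 without camta6-5 control replicate 1, 8 without wild-type control replicate 1, 10 without wild-type control replicate 3) and 16 to 30 lower. The interaction gave 4318 to 4817 positive and 3433 to 4066 negative genes.

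Without the 5 libraries richest in 18S rRNA, 2796 genes were higher and 2458 lower with NaCl in camta6-5, 3 and 1 between genotypes without NaCl, and 2607 and 1970 in the interaction. That fit has fewer libraries, 1 in each camta6-5 group, which is assumed to vary like the other groups. In it 17 of 242 results of named genes no longer passed, among them the interactions of AVP1 (adjusted p = 0.088), RD29B (0.0677) and ABI4 (0.533). Genes called in the same direction in both responses numbered 8664, 2447 at 2-fold in both, a stricter threshold, and 7712 to 8610 leaving out 1 library. Those in opposite directions numbered 235 to 441 (254 without camta6-5 control replicate 1, 235 without camta6-5 NaCl replicate 1, 271 without camta6-5 NaCl replicate 3).

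The ABRE odds ratio for a positive interaction was 0.793 at 500 bases and passed there (adjusted p = 6.58e-05), and that for a negative one was 1.18 to 1.40 over the alternatives. The heat shock list did not pass between genotypes without NaCl (0 of 17 genes called, camera adjusted p = 0.4, and 0.84 with an estimated correlation). Leaving out 1 library, its camera adjusted p was 0.0013 to 0.47, and it turned from lower to higher without camta6-5 control replicate 3 (0.028). The cause was not tested for either. Leaving out 1 library, 1705 of 1740 values of named genes kept direction and side of the threshold, 25 no longer passed and 10 newly passed. Of the 110 list results, 30 passed with the preset correlation, and all 30 no longer passed with an estimated one. With fry 37 newly passed and 1 no longer passed. Libraries of the same number correlated by 0.039 on average after group means were removed (-0.22 to 0.27), and with the block 240 of 242 named results kept their side. A count limits what is seen of HKT1, with 2 counts in all.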

Other observations

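The test behind the 6 further lists was chosen only after the data were seen, and the ER body list was built from genes that had been seen to move here, so its direction is not independent evidence. All 12 tested ER body genes fell with NaCl in both genotypes, with medians of -8.23 in wild type and -1.70 in the libraries labelled camta6-5 on the log2 scale. Proteasome subunit genes, which encode the protease that degrades ubiquitinated proteins, rose in wild type in 26 of 27 cases, while in camta6-5 3 rose and 9 fell, and 24 had a negative interaction (camera adjusted p = 3.1e-11, and adjusted p = 0.2 with an estimated correlation). Of 56 nucleolar and rRNA processing genes 39 rose and 6 fell in wild type, 5 rose and 16 fell in camta6-5, and 42 had a negative interaction and 4 a positive one (camera adjusted p = 6.1e-11, and adjusted p = 0.2 with an estimated correlation). Cytosolic ribosomal protein genes fell in 53 of 84 cases and rose in 17 in wild type, and fell in 56 and rose in 7 in camta6-5. Organelle ribosomal protein genes fell in 12 of 16 and 4 of 16 cases, and histone genes rose in 19 of 46 and fell in 17 in wild type, and rose in 10 and fell in 22 in camta6-5. Without NaCl, camera with the preset correlation put nucleolar and rRNA processing genes higher in camta6-5 (1 of 56 called, adjusted p = 5e-10). So it did for cytosolic ribosomal protein genes (0 of 84, 3e-09) and histone genes (1 of 46, 5.4e-07). With an estimated correlation these camera adjusted p were 0.28, 0.44 and 0.28.

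The fixed lists not described above moved as follows with NaCl in wild type. Of the CAMTA family 5 of 6 rose and 0 fell, of ABA metabolism 6 of 12 rose and 3 fell, of ethylene 8 of 15 and 6, of aquaporins 7 of 15 and 5, of gibberellin 9 of 21 and 6, of osmoprotectants 5 of 15 and 7, and of reserve mobilisation 7 of 19 and 8. Calcium sensing rose in 5 of 27 and fell in 17, reactive oxygen species in 3 of 20 and 11, heat shock in 2 of 17 and 10, CBF and DREB factors in 1 of 7 and 5, and salicylic acid and defence in 0 of 11 and 7. The markers of other seed parts were few, with 1 of 4 endosperm genes risen and 1 fallen, and 0 of 3 seed coat genes risen and 1 fallen. Adjusted over the list alone, the counts differed for ethylene (9 and 6) and heat shock (2 and 9). Camera with the preset correlation passed calcium sensing (adjusted p = 0.022), the CAMTA family (0.03) and salicylic acid and defence (0.032), with adjusted p of 0.36, 0.45 and 0.47 with an estimated correlation. The CAMTA family also passed in the interaction, with 3 of 6 genes negative and 0 positive (camera adjusted p = 0.049, and 0.71 with an estimated correlation). With NaCl, 5 of its 6 genes were lower in camta6-5 and 1 higher (camera adjusted p = 0.17).

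Named after their values were seen, 3 more genes differed between the genotypes at both treatments. APUM7, on chromosome 1 within 2 Mb of AT1G80490, had 0 counts in all 6 wild-type libraries, and 182 and 295 counts over the camta6-5 control and camta6-5 NaCl libraries. MRD1 had 86 and 92 counts in wild-type control and NaCl, and 5 and 10 in camta6-5. AT5G33390, which lies beside AT5G33395, had 4.74 ± 0.28 CPM in wild-type control and 1.06 ± 0.106 CPM in camta6-5 control (SD, n = 3).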
